A study of Homo sapiens with 21 samples.

How the data were processed

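Messenger RNA was sequenced from 21 libraries of HEK 293FT cells, in 7 groups of 3. Per the labels' protocols, the cells were transfected with plasmids by Lipofectamine, RNA was taken 48 h after transfection, and stranded libraries were made from polyadenylated RNA. Per the submitters' processing notes, the upstream tools were FastQC, STAR, HOMER, DESeq2 1.14.1 and R 3.3.2, and the genome build was hg19.

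The authors deposited a table of FPKM values (fragments per kilobase of exon per M) for 27142 genes in all 21 libraries. Per the file headers, HOMER counted reads in exons on the sense strand, condensed transcripts to genes and wrote FPKM. The authors also deposited 4 tables of their own comparisons. Per the file headers, each holds a mean normalized count per gene, treated here as a signal that is never negative. The same deposited tables hold a log2 fold change and an adjusted p-value per gene, which were used only as the authors' values. In each of the 4 tables, 22 to 25 gene names had been turned into calendar dates and were left out.

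FPKM values are not counts. Multiplying each value by the gene's exon length gave whole reads, within 0.1, for 95.6% to 99.5% of the values of a library. The depth recovered in this way was 21.4 to 39.5 M reads per library, of which 84.8% to 86.0% lay in genes. The recovered reads were 1.96 to 1.99 times the authors' mean counts at the median gene; the reason is not stated. The other 3 deposited comparison tables, those without arrays, share the same mean counts, which match 15 libraries, and the table for the arrays was normalized on the other 6. No library duplicated another of its own group, and libraries of different groups were not compared for this. Over replicate pairs, chi-square per degree of freedom of the recovered reads was 2.25 to 13.03, where sampling noise of independent reads gives about 1. With recovered reads at 1.96 to 1.99 times the authors' counts, reads may not be independent, and sampling alone may then give more than 1.

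Genes with at least 1 FPKM in at least 3 libraries were tested (13679 genes). Values were taken as log2(FPKM + 1), so every fold change here understates the change of low genes. One linear model over the 7 groups and all 21 libraries was fitted with limma 3.58.1 in R 4.3.3, with an intensity trend in the variance. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Targeted genes were also given an exact two-sided permutation test, which with 3 libraries against 3 cannot go below 0.1. The labels call the replicates biological, with no further detail, so p-values measure the spread between these samples. The labels give the replicates only a shared number, so the main model has no replicate term.

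Before the data were examined, 23 gene lists were fixed and tested in the 4 main comparisons (92 tests) with camera at a preset correlation of 0.01, and again with an estimated correlation. P-values were adjusted over the 92 tests. The rule for named genes was fixed at the same time. It takes both target genes, the 10 largest rises and 10 largest falls among called genes whose libraries do not overlap, and up to 5 genes per direction from the authors' table where fewer than 5 were called. It also takes up to 4 called members per list with the smallest p, and the 5 largest changes per direction for differences between methods and between controls. Genes named outside this rule are marked as such, and not every gene that the rule takes is named.

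The tests were run first on simulated data with 200 changed genes of 13679. For the ANXA4 shRNA comparison, 48% of changes of 0.25 log2, 90% of changes of 0.5 and 96% of changes of 1 were recovered, with 4 false calls among 171. For the RfxCasR B4GALNT1 comparison the shares were 42%, 88% and 92%, with 3 false calls among 164. For the array comparison the shares were 42%, 94% and 98%, but 35 of 202 calls were false. The simulated libraries had the spreads of the real groups, which are larger for the arrays. With only the 6 array libraries in the model, 8 of 140 calls were false, and 16%, 58% and 94% were recovered. The list test, with the preset correlation, recovered 5 of 5 shifted lists in each of the 4 comparisons, with 0 false lists. The simulated data were matched to the real groups in spread, and no match in correlation between genes is stated. In the real data the estimated correlation was 0.39 for ribosomal proteins and 0.452 for proteasome subunits. The 0 false lists therefore cannot show how often lists of correlated genes are called falsely.

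Alternatives fixed beforehand were another pseudocount, other filters, median-centred and quantile-normalized values, models with only the groups compared, no variance trend, a replicate block, a stricter threshold, voom on the recovered reads with median-ratio size factors, the authors' own counts of calls, and leaving out each library. Added after seeing the data were a model without the array libraries, a separate variance for them, and exchanged labels of the 2 array groups. Transcripts of GENCODE v29 (GRCh38) were matched by gene symbol for tests of short sequences in 3' untranslated regions. All coordinates are hg19, from the deposited table. The shRNA and guide sequences are not given in the sources used here.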

Results

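Transcriptomes were compared after knockdown of 2 genes by 2 methods in HEK 293FT, a human embryonic kidney line that expresses the SV40 large T antigen. Short hairpin RNAs (shRNAs) are processed into small RNAs that guide Argonaute proteins to messenger RNA. RfxCasR is an RNA-guided CRISPR nuclease that cuts RNA, directed either by a single guide RNA (gRNA) or by an array of guides. The 7 groups had 3 replicates each: a non-targeting (NT), an ANXA4 and a B4GALNT1 shRNA, RfxCasR with an NT or a B4GALNT1 gRNA, and RfxCasR with an NT or an ANXA4 array. Per its title, the series asks how specific RfxCasR and matching shRNAs are. Depth recovered from the FPKM values was 21.4 to 30.7 M reads in the 15 shRNA and single-guide libraries and 34.7 to 39.5 M in the 6 array libraries.

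ANXA4 encodes a calcium-dependent phospholipid-binding annexin (NM_001153, hg19 chromosome 2, 69969106 to 70053609, plus strand). With the ANXA4 shRNA it fell from 5.90 ± 0.378 FPKM (SD, n = 3) to 2.40 ± 0.22, a reduction of 59.3%. The change was -1.02 log2 (SE 0.076, limma adjusted p = 1.72e-09). B4GALNT1 encodes an N-acetylgalactosaminyltransferase of ganglioside synthesis (NM_001478, hg19 chromosome 12, 58019678 to 58027022, minus strand). It fell by 31.8% with its shRNA, from 4.08 ± 0.179 to 2.78 ± 0.183 FPKM (-0.43 log2, SE 0.075, limma adjusted p = 0.000131). With the B4GALNT1 gRNA it fell by 62.4%, from 5.89 ± 0.907 to 2.21 ± 0.167 FPKM (-1.09 log2, SE 0.075, limma adjusted p = 1.67e-07). Each of these 3 changes separated all libraries of the groups, and the exact permutation p was 0.1, the smallest that 3 against 3 can give.

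The array libraries went against their labels. ANXA4 was at 7.03 ± 0.24 FPKM (n = 3) in the libraries labelled ANXA4 array and at 3.03 ± 0.427 in those labelled NT array, a difference of 1.00 log2 (SE 0.076, limma adjusted p = 5.37e-07). The 6 single-guide RfxCasR libraries lay between 6.56 and 7.60 FPKM. The authors' deposited table for this comparison gives the opposite sign, -1.207 log2 (adjusted p = 7.53e-17). Across 12219 genes the fold changes from the labelled columns correlated with the authors' deposited table at -0.951, against 0.952 to 0.985 in the other 3 comparisons. Genes are not independent replicates. Directions for the arrays are therefore given below for the libraries as labelled, with the sign in the authors' deposited table beside them.

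**Figure D1:**
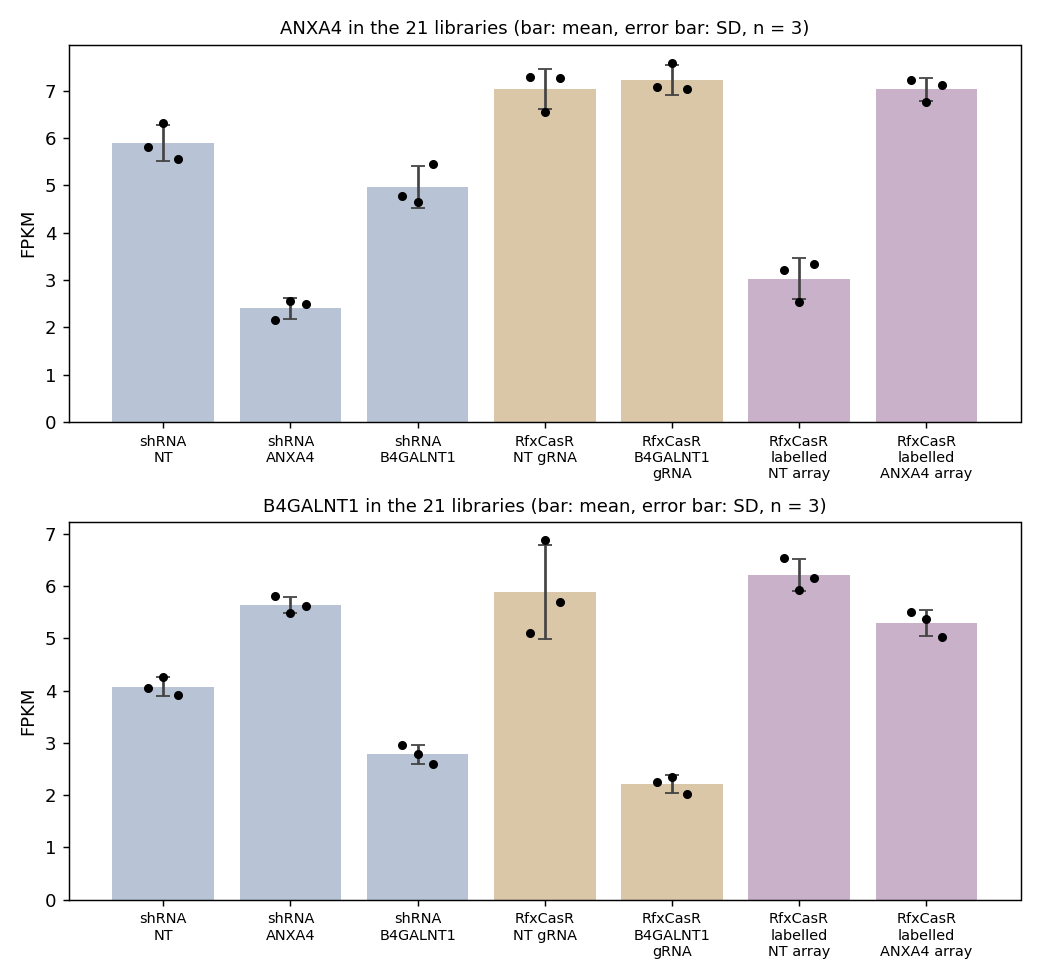
FPKM of ANXA4 (top) and B4GALNT1 (bottom) in the 21 libraries, by group as labelled; bars are means, error bars SD, points the 3 libraries of a group. ANXA4 was low in the ANXA4 shRNA libraries (2.40) and in the libraries labelled RfxCasR NT array (3.03), and B4GALNT1 was lowest with the B4GALNT1 gRNA (2.21).

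The targets were also measured under the reagents for the other gene. With the ANXA4 shRNA, B4GALNT1 rose from 4.08 to 5.64 ± 0.156 FPKM (0.39 log2, limma adjusted p = 0.000246). With the B4GALNT1 shRNA, ANXA4 fell from 5.90 to 4.96 ± 0.439 FPKM (-0.21 log2, limma adjusted p = 0.0307). With the B4GALNT1 gRNA, ANXA4 differed by 0.03 log2 from its control, which was not called (limma adjusted p = 1). Nor was B4GALNT1 between the libraries labelled ANXA4 array (5.30 ± 0.249 FPKM) and NT array (6.21 ± 0.303), at -0.19 log2 (limma adjusted p = 0.336; 0.24 log2 with the opposite sign in the authors' deposited table). B4GALNT1 in the NT shRNA libraries, 4.08 FPKM, lay below its level of 5.89 in the RfxCasR NT gRNA libraries.

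The ANXA4 shRNA changed 7089 of 13679 genes (limma), 3497 higher and 3592 lower. Of these, 147 changed by at least 2-fold on the log2(FPKM + 1) scale, which understates the change of low genes. Groups did not overlap for 60.9% of genes, where chance gives 10%. The largest rise of a protein-coding gene was in UHMK1, a serine/threonine kinase, from 3.57 ± 0.0711 to 17.2 ± 1.15 FPKM (1.99 log2, SE 0.057, limma adjusted p = 2.63e-15). LPCAT3, a lysophospholipid acyltransferase, rose from 6.07 to 22.4 FPKM. TPRG1L rose from 6.87 to 24.9, NSA2, a ribosome biogenesis factor, from 20.2 to 61.5, and MCU, the pore of the mitochondrial calcium uniporter, from 6.18 to 18.8 FPKM. PRTG (1.44 log2), TRIP10 (1.42) and SYNGR2 (1.38) were also among the 10 largest rises. So were MIR4745 and MIR6827, short annotations inside PTBP1 and AMOTL2 on the same strand, whose reads cannot be told apart from those of the host. For several of the protein-coding genes the NT shRNA libraries were below every other group: over the 4 RfxCasR groups LPCAT3 was at 15.4 to 17.3, NSA2 at 55.4 to 73.6, MCU at 17.6 to 20.9, TRIP10 at 16.3 to 20 and SYNGR2 at 58.6 to 75.8 FPKM. TPRG1L lay between, at 13.6 to 15.7, and UHMK1 (4.64 to 6.07) and PRTG (2.37 to 2.70) stayed nearer to the NT shRNA level.

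RPLP1, a protein of the ribosomal stalk, fell from 1550 ± 58.8 to 444 ± 5.16 FPKM with the ANXA4 shRNA (-1.80 log2, SE 0.046, limma adjusted p = 1.06e-15). POLR3GL, an RNA polymerase III subunit, fell from 30.1 to 8.96 FPKM and ACBD3, a Golgi protein, from 33.6 to 10.9. DUT, the dUTPase, fell from 55.9 to 20 and SET from 188 to 68.9 FPKM. BCL2L12 (-1.41 log2), PITPNB (-1.41), HIBADH (-1.40), AGO1 (-1.38) and TSPYL2 (-1.38) completed the 10 largest falls. AGO1, an Argonaute protein, went from 11.4 to 3.78 FPKM.

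Of 23 S phase genes measured, 21 fell and 0 rose with the ANXA4 shRNA (the same counts adjusted over the list alone), with a median of -0.314 log2 (camera adjusted p = 2.6e-09). This call held with an estimated correlation (adjusted p = 0.02). CCNE1, cyclin E, fell from 15.7 to 6.63 FPKM, and the replicative helicase subunits MCM5 and MCM6 fell by 0.67 and 0.60 log2. Of 77 cytosolic ribosomal protein genes, 48 fell and 1 rose (50 and 1 adjusted over the list alone). The camera adjusted p was 2.86e-08, and the adjusted p was 0.777 with an estimated correlation. RPLP2 fell from 926 to 377 and RPL14 from 394 to 178 FPKM; reads of these genes can be shared with processed pseudogenes.

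Among 21 genes of the integrated stress response and amino acid supply, 15 fell and 1 rose (16 and 1 adjusted over the list alone) with a median of -0.432 log2. The camera adjusted p was 0.000109, and the adjusted p was 0.454 with an estimated correlation. ATF4, the transcription factor of this response, fell from 227 to 127 FPKM and DDIT4 from 258 to 142. Of 21 cholesterol synthesis genes, 15 rose and 1 fell (15 and 2 adjusted over the list alone), among them SREBF2 (0.76 log2), MSMO1 (0.72) and DHCR7 (0.60). The camera adjusted p was 4.23e-05, and the adjusted p was 0.403 with an estimated correlation. Proteasome subunits (17 rose and 6 fell of 30, with the same counts adjusted over the list alone; camera adjusted p = 0.0216) and hypoxia and glycolysis genes (13 rose and 5 fell of 25, likewise; camera adjusted p = 0.0228) were called too. Their adjusted p was 0.816 and 0.777 with an estimated correlation. PSMA6 rose from 46.0 to 101 FPKM (79.5 to 106 in the RfxCasR groups), ALDOA, aldolase A, rose from 832 to 1745 (1283 to 1723 in the RfxCasR groups), and GAPDH fell from 2048 to 1512.

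The other lists were not called with the ANXA4 shRNA, although single members were (limma, counts the same adjusted over the list alone unless given). Of 7 annexin genes, 1 rose and 2 fell (camera adjusted p = 0.499), with ANXA6 (-0.35 log2), ANXA5 (-0.26) and ANXA7 (0.13) first by p. Of 11 ganglioside and B4GALNT enzymes, 2 rose and 4 fell (camera adjusted p = 0.982), with B4GALNT3 (0.72 log2), B4GALNT4 (-0.67), ST3GAL2 (0.30) and B3GALT4 (-0.40) first by p. Of 21 interferon-stimulated genes, 1 rose and 5 fell (camera adjusted p = 0.873), among them BST2 (-1.27 log2), USP18 (0.34) and IFI6 (-0.33). Of 5 NF-kB and inflammatory genes, 2 rose and 2 fell (camera adjusted p = 0.822), with RELB (1.05 log2), TNFAIP3 (0.41), NFKB1 (-0.33) and NFKB2 (-0.20) first by p. Of 13 genes of the RNA interference machinery, 4 rose and 5 fell (camera adjusted p = 0.982), with AGO1 (-1.38 log2), DICER1 (0.54), XPO5 (0.33) and TNRC6A (0.47) first by p. Of 25 let-7 targets, 12 rose and 3 fell (camera adjusted p = 0.0849), with LIN28B (0.78 log2), ARID3A (-0.82), TRIM71 (0.77) and IGF2BP1 (0.43) first by p. Of 17 RNA decay and stress granule genes, 4 rose and 4 fell (camera adjusted p = 0.461), with G3BP2 (0.65 log2), DCP1A (0.88), ADAR (-0.50) and SMG5 (0.57) first by p. Of 20 unfolded protein response genes, 10 rose and 3 fell (camera adjusted p = 0.371, 10 and 4 adjusted over the list alone), with SEL1L (-0.70 log2), HSPA5 (0.39), DNAJB11 (0.48) and PDIA6 (-0.24) first by p. Of 15 heat shock genes, 6 rose and 5 fell (camera adjusted p = 0.371), with DNAJB1 (0.91 log2), HSPA8 (0.50), HSPA1A (0.50) and HSP90AB1 (-0.19) first by p. Of 18 p53 targets, 2 rose and 5 fell (camera adjusted p = 0.66), with BBC3 (-0.65 log2), FDXR (-0.46), DDB2 (-0.44) and BAX (-0.29) first by p.

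Of 15 immediate early genes, 7 rose and 2 fell (camera adjusted p = 0.257), with JUN (0.69 log2), EGR1 (1.08), CTGF (-0.43) and KLF4 (0.47) first by p. Of 24 genes of G2 and mitosis, 5 rose and 11 fell (camera adjusted p = 0.195), with KIF20A (-0.45 log2), TOP2A (-0.37), NUSAP1 (-0.38) and AURKB (-0.23) first by p. Of 16 histone genes, 0 rose and 4 fell (camera adjusted p = 0.277, 0 and 3 adjusted over the list alone), with HIST1H1C (-0.30 log2), HIST1H2BK (-0.37), HIST2H2BE (-0.45) and HIST1H3B (-0.64) first by p. Of 40 nuclear oxidative phosphorylation genes, 18 rose and 7 fell (camera adjusted p = 0.11), with ATP5O (0.98 log2), UQCR11 (-0.66), UQCRQ (-0.80) and NDUFB10 (0.45) first by p. Of 20 matrix and adhesion genes, 10 rose and 8 fell (camera adjusted p = 0.982), with COL4A2 (0.95 log2), ITGB1 (-1.04), AGRN (-0.68) and SPARC (-0.48) first by p. Of 6 markers of blood, fibroblast and endothelial cells, 2 rose and 2 fell (camera adjusted p = 0.759), with COL1A1 (-0.40 log2), ACTA2 (-0.60), COL3A1 (0.29) and LUM (0.43) first by p. Of 15 HEK 293 identity genes, 6 rose and 3 fell (camera adjusted p = 0.543), with VIM (0.51 log2), NES (-0.84), NEFL (0.53) and KRT18 (-0.57) first by p. Members of the called lists not named above were SLC7A5 (-0.60), TRIB3 (-0.56), FDFT1 (0.49), HK2 (-0.83), LDHA (0.49), RPA2 (-0.76), RPL13A (-0.78), PSMD11 (0.40), PSMB6 (0.61) and PSMA1 (-0.35 log2).

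The B4GALNT1 shRNA changed 6077 genes (limma), 2523 higher and 3554 lower. Of these, 63 changed by at least 2-fold on the log2(FPKM + 1) scale, which understates the change of low genes. Groups did not overlap for 55.5% of genes, where chance gives 10%. After centring each library on its median the split was 3162 higher and 2775 lower, so the balance of directions depended on the scaling. TPRG1L rose from 6.87 ± 0.225 to 25.9 ± 1.34 FPKM (1.77 log2, SE 0.048, limma adjusted p = 7.78e-15). CREBL2 rose from 2.96 to 12.4, MCU from 6.18 to 20.6, NSA2 from 20.2 to 60.8 and LPCAT3 from 6.07 to 17.1 FPKM. CSTB, the protease inhibitor cystatin B (1.27 log2), MKRN2 (1.19), TMEM59L (1.19) and CAP1, a regulator of actin (1.17), followed. The RfxCasR NT gRNA libraries already had levels of 17.6 for MCU, 55.4 for NSA2, 16.4 for LPCAT3, 88 for CSTB, 20 for MKRN2, 5.6 for TMEM59L and 101 for CAP1, and 8.51 FPKM for CREBL2, so that the NT shRNA libraries were the low group. SNORD124, a small nucleolar RNA inside MED24, was listed at 0 in all NT shRNA libraries and at 1.39 ± 0.864 FPKM with this shRNA. At 102 bases and close to the 1 FPKM used as a filter, this rise lies near the floor.

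TXNIP, a thioredoxin-binding arrestin-like protein, fell from 60.9 ± 0.507 to 16.6 ± 0.971 FPKM with the B4GALNT1 shRNA (-1.82 log2, SE 0.054, limma adjusted p = 1.14e-14). MCRIP1 fell from 145 to 44.1 FPKM, and the sorting nexins SNX17 and SNX12 fell from 57.9 to 18.8 and from 44.8 to 15.5. RFXANK, a subunit of a regulator of MHC class II genes, fell from 32.4 to 11 FPKM. FGFRL1 (-1.36 log2), TESK2 (-1.24), TMEM9B (-1.16) and CENPBD1 (-1.14) fell as well, with MIR4639, which lies inside MYLIP. Falls given for the shRNAs are against the NT shRNA libraries alone, which may be high for some genes. Of 1758 genes called lower with both shRNAs, 86.2% were also lower with the RfxCasR NT gRNA than with the NT shRNA. Of 1657 called higher with both, 86.7% were also higher. Both sides of this count use the same NT shRNA libraries.

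Of 18 p53 target genes, 13 fell and 0 rose with the B4GALNT1 shRNA (the same counts adjusted over the list alone), with a median of -0.258 log2 (camera adjusted p = 0.000842). This call held with an estimated correlation (adjusted p = 0.0422). MDM2, the ubiquitin ligase of p53, fell from 11.7 to 7.71 FPKM, AEN from 31.3 to 20.6 and DDB2 from 13.6 to 9.20. Of 21 cholesterol synthesis genes, 15 rose and 1 fell (the same adjusted over the list alone; camera adjusted p = 2.3e-07, and adjusted p = 0.245 with an estimated correlation). HMGCS1 rose from 35.4 to 61.5 FPKM (45.7 to 63 in the RfxCasR groups), and LSS was the member that fell, from 33.6 to 20.3. Of 15 heat shock genes, 10 rose and 1 fell (the same adjusted over the list alone; camera adjusted p = 0.00015, and adjusted p = 0.403 with an estimated correlation). DNAJB1 rose from 51.3 to 95.6 FPKM, and the member that fell was HSF1, from 56.1 to 42.6.

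Further lists called with the B4GALNT1 shRNA were hypoxia and glycolysis (13 rose and 1 fell of 25), proteasome subunits (19 and 3 of 30), integrated stress response (0 and 10 of 21), S phase (0 and 10 of 23) and unfolded protein response (7 and 2 of 20). Adjusted over the list alone the counts were 13 and 1, 19 and 4, 0 and 10, 1 and 11, and 7 and 2. Their camera adjusted p was 0.000294, 0.0003, 0.0216, 0.027 and 0.0487 in that order. With an estimated correlation the adjusted p was 0.709, 0.777, 0.777, 0.454 and 0.454. LDHA, lactate dehydrogenase A, rose from 668 to 1015 FPKM (918 to 1118 in the RfxCasR groups), SLC7A11, a cystine transporter, fell from 4.83 to 1.68, and HSPA5, the endoplasmic reticulum chaperone, rose from 126 to 173.

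The other lists were not called with the B4GALNT1 shRNA, although single members were (limma, counts the same adjusted over the list alone unless given). Of 7 annexin genes, 1 rose and 2 fell (camera adjusted p = 0.982), with ANXA3 (0.57 log2), ANXA7 (-0.19) and ANXA11 (-0.11) first by p. Of 11 ganglioside and B4GALNT enzymes, 3 rose and 3 fell (camera adjusted p = 0.662), with B4GALT6 (-0.71 log2), B4GALNT3 (0.64), ST3GAL5 (-0.80) and B4GALT5 (0.39) first by p. Of 21 interferon-stimulated genes, 2 rose and 5 fell (camera adjusted p = 0.79, 2 and 4 adjusted over the list alone), with OAS3 (0.27 log2), IFI6 (-0.23), IFIT5 (0.25) and USP18 (-0.21) first by p. No member of the 5 NF-kB and inflammatory genes measured was called. Of 13 genes of the RNA interference machinery, 2 rose and 4 fell (camera adjusted p = 0.982), with DICER1 (0.62 log2), XPO5 (-0.37), AGO3 (-0.55) and TNRC6C (-0.48) first by p. Of 25 let-7 targets, 10 rose and 6 fell (camera adjusted p = 0.242, 12 and 6 adjusted over the list alone), with ARID3B (-0.88 log2), E2F5 (0.69), CCND2 (-0.86) and TRIM71 (0.66) first by p. Of 17 RNA decay and stress granule genes, 4 rose and 3 fell (camera adjusted p = 0.657), with G3BP2 (0.89 log2), DCP1A (0.65), ADAR (-0.28) and DCP2 (-0.20) first by p.

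Of 15 immediate early genes, 5 rose and 1 fell (camera adjusted p = 0.0896, 4 and 1 adjusted over the list alone), with JUN (0.81 log2), DUSP1 (0.83), CTGF (-0.76) and MYC (0.19) first by p. Of 24 genes of G2 and mitosis, 3 rose and 10 fell (camera adjusted p = 0.347), with CDK1 (-0.61 log2), CCNA2 (-0.54), CCNB1 (0.33) and KIF20A (-0.33) first by p. Of 16 histone genes, 1 rose and 2 fell (camera adjusted p = 0.98, 0 and 1 adjusted over the list alone), with HIST1H1C (-0.22 log2), HIST1H3H (-0.51) and HIST1H2BK (0.21) first by p. Of 77 ribosomal protein genes, 7 rose and 6 fell (camera adjusted p = 0.982, 5 and 3 adjusted over the list alone), with RPL34 (-0.52 log2), RPLP0 (-0.22), RPS13 (0.19) and RPL22 (0.17) first by p. Of 40 nuclear oxidative phosphorylation genes, 10 rose and 3 fell (camera adjusted p = 0.125, 8 and 3 adjusted over the list alone), with ATP5O (0.90 log2), UQCRC2 (-0.41), NDUFB10 (0.31) and ATP5B (0.37) first by p. Of 20 matrix and adhesion genes, 5 rose and 7 fell (camera adjusted p = 0.889), with COL4A2 (0.83 log2), SPARC (-0.33), AGRN (-0.36) and COL18A1 (-0.36) first by p. Of 15 HEK 293 identity genes, 5 rose and 1 fell (camera adjusted p = 0.257), with VIM (0.50 log2), SIX2 (-0.45), NEFM (0.42) and KRT18 (0.26) first by p. Members of the called lists not named above were PDIA6 (0.25), DNAJB9 (0.91), PDIA4 (0.20), CTH (-0.85), MTHFD2 (-0.33), PSPH (-0.30), HSPA8 (0.45), HSP90AA1 (0.27), TP53INP1 (-0.54), FDFT1 (0.56), SREBF2 (0.51), ALDOA (0.95), GAPDH (0.29), SLC2A1 (0.34), MCM5 (-0.78), MCM3 (-0.34), MCM2 (-0.34), E2F1 (-0.45), PSMA6 (0.93), PSMB2 (0.30), PSMB6 (0.45) and PSMD2 (-0.24 log2).

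Both shRNAs were compared with the same NT libraries, and 3415 genes were called in the same direction with both, 1657 higher and 1758 lower, against 579 in opposite directions. Independent lists of these sizes would share 645 higher and 933 lower genes. In 50 simulated data sets of unchanged groups with shared controls, no gene was called with both. Since no gene differed in those data sets, this cannot show how many shared calls the controls add where many genes are called. The covariance of the 2 sets of fold changes was 0.0513, against 0.0064 from the simulated shared controls, a difference of 0.0449. The correlation across genes was 0.543, against 0.5 simulated. The 3 NT libraries are too few to be split, so part of the excess may come from the shared controls. Besides TPRG1L, MCU, NSA2 and LPCAT3, the rise in DNAJB1 (from 51.3 to 97.3 and to 95.6 FPKM) and the fall in MCM5 (from 89.4 to 55.9 and to 51.8 FPKM) were common to both.

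With the B4GALNT1 gRNA, the gene called by limma was B4GALNT1 itself, with 0 genes higher and 1 lower. At an unadjusted p under 0.05 there were 523 genes, and voom on the recovered reads also called 1 gene. RFXANK, the other gene in the authors' deposited table at an adjusted p under 0.05 (-0.388 log2, adjusted p = 0.00993), went from 28.3 ± 0.492 to 21.8 ± 1.3 FPKM, which was not called (-0.36 log2, limma adjusted p = 0.0849). Groups did not overlap for 11.8% of genes, where chance gives 10%. Without the 6 array libraries in the model 3 genes were called, and with a separate variance for those libraries 4. The added genes, named after their values were seen, were RFXANK, TCTA (-0.338 log2) and MBLAC1 (-0.639 log2).

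No member of any of the 23 lists was called over all genes with the B4GALNT1 gRNA. Adjusted over the list alone, 5 ribosomal protein genes were higher and 1 lower, 1 histone gene higher and 1 lower, and 1 interferon-stimulated gene lower. Camera called small shifts in ribosomal protein genes (median 0.036 log2, adjusted p = 1.56e-07), cholesterol synthesis (0.056, adjusted p = 3.87e-05), hypoxia and glycolysis (0.018, adjusted p = 0.00558) and immediate early genes (-0.071, adjusted p = 0.00126). With an estimated correlation the adjusted p was 0.777, 0.403, 0.777 and 0.454.

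In the array comparison as labelled, limma called 39 genes, 20 higher and 19 lower in the libraries labelled ANXA4 array. Groups did not overlap for 10.3% of genes, where chance gives 10%. The annexin ANXA11 differed with ANXA4, at 49.7 ± 0.753 against 35.7 ± 1.29 FPKM (0.47 log2, SE 0.035, limma adjusted p = 5.37e-07). PPP1R15A, a regulatory subunit of protein phosphatase 1 induced by stress, was at 34.1 against 24.9 FPKM. HIST2H2BE (3.81 against 7.46 FPKM) and HIST3H2A (38.6 against 62.7), histone genes, lay the other way. The authors' deposited table has the opposite sign for ANXA11 (-0.472), PPP1R15A (-0.44), HIST2H2BE (0.984) and HIST3H2A (0.714). All 7 genes called in both had opposite signs.

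The remaining genes of the rule, with differences as labelled and the opposite sign in the authors' deposited table, were SNORD65 (0.92 log2), LOC100507291 (0.70), LINC00937 (0.58), ART5 (0.44), TTLL3 (0.43) and KCTD13 (0.41). On the lower side as labelled were MIR658 (-0.78), C19orf81 (-0.74), HES4 (-0.53), MIR636 (-0.47), HMX1 (-0.47), ZNF771 (-0.43), B3GALT6 (-0.31) and CEBPA (-0.30). None of these genes, on either side, had an adjusted p under 0.05 in the authors' deposited table. The lowest there was 0.0874, for ZNF771, so only the sign can be set beside them. SNORD18B, inside RPL4, was listed at 0 in the libraries labelled NT array and at 2.47 ± 0.482 FPKM in those labelled ANXA4 array. This annotation has 69 bases and a mean count of 0.7455 in the authors' deposited table, where it was not called. Its difference thus lies near the floor. The array libraries had a larger spread between replicates, with a median SD of 0.0984 and 0.0822 log2 against 0.0592 to 0.0661 in the other groups. The count was 3 with only these 6 libraries in the model (SNORD18B, ANXA4 and ANXA11), 7 with a separate variance, 114 with voom and 23 without replicate 2 labelled ANXA4 array.

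Among the lists, camera called ribosomal protein genes (0 called of 77, 4 higher adjusted over the list alone, median 0.067 log2, adjusted p = 1.58e-09), hypoxia and glycolysis (0 of 25, also adjusted over the list alone; median 0.074, adjusted p = 0.00812) and annexins (1 of 7, also adjusted over the list alone; median 0.026, adjusted p = 0.00568) as higher in the libraries labelled ANXA4 array. The adjusted p was 0.739, 0.777 and 0.154 with an estimated correlation, and the array table of the authors implies the opposite direction.

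**Figure D2:**
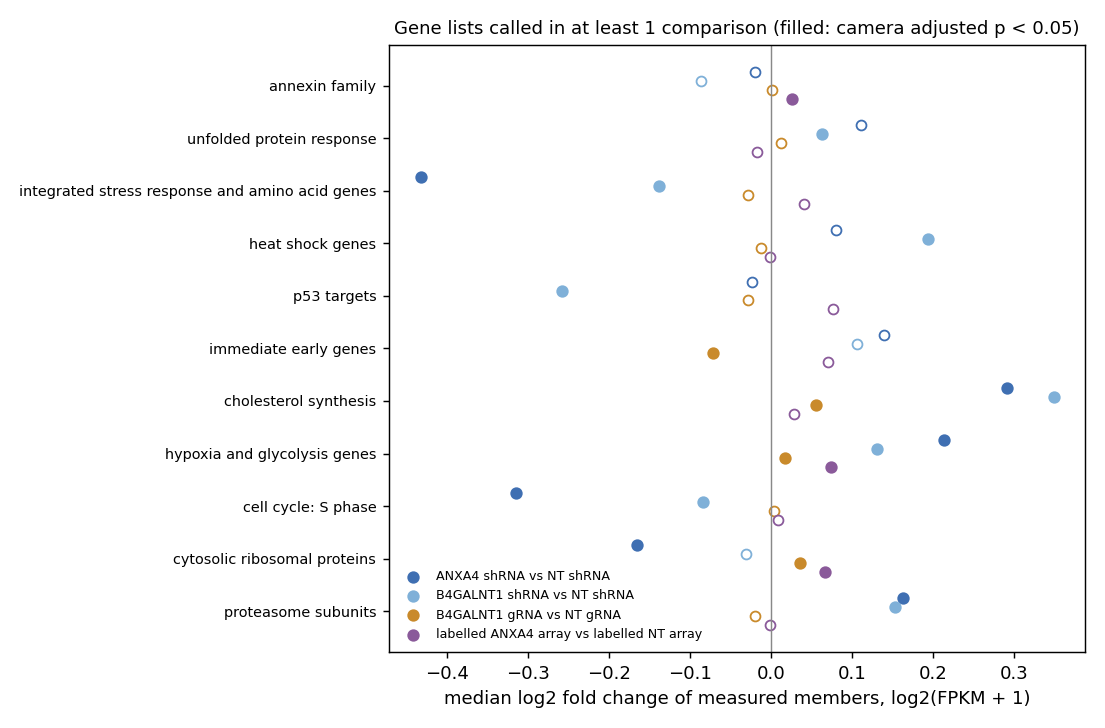
Median log2 fold change, on the log2(FPKM + 1) scale, of the measured members of each gene list called in at least 1 of the 4 main comparisons; filled points passed camera at an adjusted p under 0.05 and open points did not, and the array comparison is drawn as labelled. S phase genes had a median of -0.314 and cholesterol synthesis genes of 0.291 with the ANXA4 shRNA.

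The methods were then compared directly. For B4GALNT1, the RfxCasR effect minus the shRNA effect differed from 0 for 4078 genes (limma), 2318 with a positive and 1760 with a negative difference. With median-centred libraries the split was 1821 and 2231. TXNIP (1.84 log2), MCRIP1 (1.65), SNX17 (1.54) and SNX12 (1.43) had the largest positive differences of protein-coding genes. The largest negative ones were in TPRG1L (-1.80), CREBL2 (-1.78), NSA2 (-1.53) and MCU (-1.47). Over the 6075 genes called with the B4GALNT1 shRNA, targets left out, the RfxCasR fold change followed that of the shRNA with a slope of 9.8e-05 (95% bootstrap interval over genes -0.0059 to 0.0066). Over all 13679 genes the signs of the 2 methods matched in 50.3%. B4GALNT1 was the 1 gene called with both methods.

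For ANXA4, the same difference with the arrays as labelled was called for 5414 genes (limma), 2818 positive and 2596 negative. As labelled, UHMK1 (-2.14 log2), TPRG1L (-1.78) and HES5 (1.78) were among the largest differences. With the labels of the 2 array groups exchanged these were -1.852, -1.658 and 0.766 log2. ANXA4 itself differed by 2.02 log2 as labelled and by 0.022 log2 with exchanged labels (SE 0.108, limma adjusted p = 0.897), where 5350 genes were called. Of the 39 genes called with the arrays, 25 were also called with the ANXA4 shRNA, 13 in the same and 12 in the opposite direction as labelled, where independent lists would give 10 of each.

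**Figure D3:**
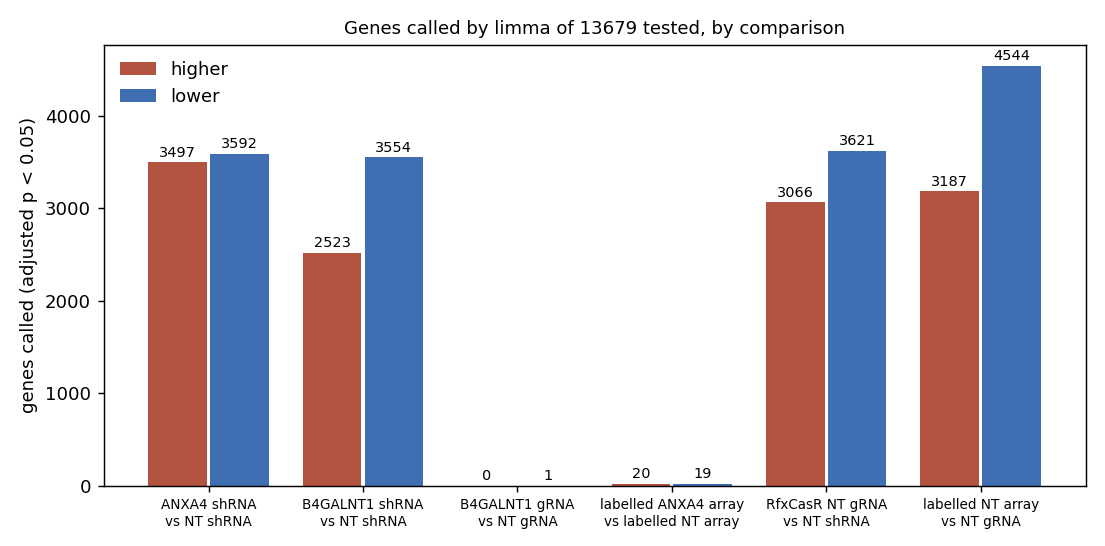
Number of genes called by limma (adjusted p under 0.05) as higher or lower in each comparison, of 13679 tested, with the array groups as labelled. The 2 shRNA comparisons and the 2 comparisons between control groups each hold from 6077 to 7731 calls, against 1 with the B4GALNT1 gRNA and 39 with the array.

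The control groups differed from each other. Between RfxCasR with the NT gRNA and the NT shRNA, 6687 genes were called (limma), 3066 higher and 3621 lower with RfxCasR. With median-centred libraries these were 3698 and 2860. The histone genes HIST1H4H (8.55 against 1.73 FPKM), HIST1H3D (3.37 against 0.331) and HIST1H4E (6.81 against 1.45) were higher with RfxCasR. Most histone messages lack a poly(A) tail, so RNA selection can shift them. So were the small RNAs SCARNA12 (1.66 log2) and SNORA14B (1.64), inside PHB2 and TOMM20. ZNF367 (5.92 against 21.3 FPKM), PTBP2, a splicing regulator (9.69 against 25.2), and LIN7B (3.79 against 9.86) were lower with RfxCasR, as were MIR555 and MIR4741 (-1.19 and -1.13 log2).

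Between the libraries labelled NT array and those with the NT gRNA, 7731 genes were called (limma), 3187 higher and 4544 lower in the arrays, or 4238 and 3421 with median-centred libraries. HIST1H2BK rose from 35.8 ± 2.01 to 95.5 ± 12.0 FPKM. The other leading items were short annotations: MIR6844, MIR6801, MIR6747 and SNORA103 were higher by 1.65 to 2.31 log2, and MIR3610, MIR5703, MIR3687-1, MIR3687-2 and MIR7705 were lower by 2.85 to 4.60 log2. MIR3687-1 and MIR3687-2 are listed at the same position. RAD21, the host of MIR3610, differed by 0.0282 log2. The array libraries were deeper (34.7 to 39.5 against 24.5 to 27.6 M reads), and 22.3% to 23.2% of their recovered reads per gene were odd numbers, against 41.3% to 43.4% in all others. The array groups and this library difference cannot be told apart in this comparison.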

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

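The tests of the array labels were chosen only after the ANXA4 values were seen, as was the use of exchanged labels. The test of genes lowered in the NT shRNA libraries was written after the spread of the libraries and some levels in the RfxCasR groups had been seen. The genes lower with both shRNAs and the 7-mers between control groups were also set beside these tests afterwards. The other tests below were written before their results.

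For differences between the methods, the test of the difference itself passed. For B4GALNT1 this held for 4078 genes, among them TXNIP (1.84 log2, RfxCasR minus shRNA), MCRIP1 (1.65), SNX17 (1.54), MIR4707 (1.53), SNX12 (1.43), TPRG1L (-1.80), CREBL2 (-1.78), SNORD124 (-1.72), NSA2 (-1.53) and MCU (-1.47). For ANXA4, with the arrays as labelled, it held for 5414 genes, among them SNORD18B (2.05), ANXA4 (2.02), MIR7706 (1.90), MIR4743 (1.79), HES5 (1.78), MIR6827 (-2.27), UHMK1 (-2.14), SNORD50B (-2.03), TPRG1L (-1.78) and SNORD124 (-1.69). With exchanged array labels only UHMK1 (-1.852), TPRG1L (-1.658) and HES5 (0.766) of these 10 kept their direction and their call. Groups of 3 were not searched for outlying libraries.

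Other splits of the same libraries were counted. For the 2 differences between methods, 3 of 100 splits gave as many genes, the real one included, a share under 0.05. The highest of the other splits gave 4109 genes for B4GALNT1 and 5915 for ANXA4. Of the 100 splits, 15 and 12, the real one included, kept each shRNA group together, as labelled or exchanged. These gave 3890 to 4109 and 5038 to 5915 genes for B4GALNT1 and ANXA4. Splits that mixed the shRNA groups gave at most 1 and 3. The share of 3 of 100 therefore depends on how many such splits were drawn, and does not test the difference between methods. The differences thus rest on the shRNA libraries. For comparisons of 3 libraries against 3, the 10 splits are too few for a share under 0.05. The real split, 1 of 10, gave 7089 genes for the ANXA4 shRNA, 6077 for the B4GALNT1 shRNA, 1 for the B4GALNT1 gRNA, 6687 between the NT gRNA and NT shRNA and 7731 between the NT array and NT gRNA, and the highest other split gave 0 in each. For the arrays, 3 of 10 splits gave as many as the real 39, and the highest other gave 200. That split set replicates 1 and 2 labelled ANXA4 array and replicate 2 labelled NT array against the other 3. Another split gave 172, with replicate 1 labelled ANXA4 array and replicates 2 and 3 labelled NT array on 1 side. These splits group the libraries differently. Differences among the array libraries beyond their groups are possible and were not tested.

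The first pattern weighed is that ANXA4 was higher in the libraries labelled ANXA4 array. A reversed sign in the authors' table, with correct columns, is argued against by ANXA4 itself: its highest value in the libraries labelled NT array was 3.34 FPKM, below the lowest of the 6 single-guide RfxCasR libraries, 6.56. An exchange of the FPKM columns of the 2 groups is consistent with the correlation of -0.951 with the authors' deposited table, and the partner group was out of place too, at 6.76 to 7.22 FPKM. With the labels exchanged, ANXA4 differed by -0.001 log2 between the NT array and NT gRNA libraries, against -1.001 as labelled. No label was changed here, and an exchange elsewhere in the handling of the samples stays open.

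The second pattern is that 7089 and 6077 genes differed with the shRNAs and 1 and 39 with RfxCasR. Scaling between libraries is argued against, since the smaller of the shRNA counts was still 5978 after quantile normalization. The larger spread of the array libraries is argued against by the 5349 genes called when the ANXA4 shRNA effects were planted in those 6 libraries. Loss of B4GALNT1 itself is argued against by the slope of 9.8e-05 between the methods, although the gRNA lowered the target more than the shRNA did. Short matches between each shRNA and 3' untranslated regions stay open, since the shRNA sequences were not used. Genes with certain 7-mers were lower, with a leading shift of -0.141 log2 for the ANXA4 shRNA and -0.053 for the B4GALNT1 shRNA. But 64 7-mers also passed between the NT array and NT gRNA, without any shRNA, among them GCGGGGG with a shift of -0.057. In size, the shift with the B4GALNT1 shRNA was not set apart from that, while the shift with the ANXA4 shRNA was larger. By rank-sum test the leading 7-mer with the B4GALNT1 shRNA, GCTGCCT, had a Bonferroni p of 1.98e-19. Between the NT array and NT gRNA the lowest was 3.97e-07, for GGGGGCT. Genes are not independent replicates, so these p-values only rank the 7-mers.

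The third pattern is that many genes rose with both shRNAs against their shared control. Noise of the 3 shared libraries is argued against, since the covariance was 8.02 times the simulated one. Of the 1657 genes called higher with both, a share of 0.867 was also higher with the RfxCasR NT gRNA than with the NT shRNA, and of the 1758 called lower with both, 86.2% were also lower. Both sides of this test use the same NT shRNA libraries that chose the genes, and unchanged groups with a shared control already matched in sign for 66.7% of genes in simulation. The test therefore cannot tell whether the NT shRNA lowered genes, and a shift of the NT shRNA libraries in both directions, or differences of plasmid, stay open. Genes with the 7-mer CTACCAA were higher by 0.14 and 0.118 log2 with the ANXA4 and B4GALNT1 shRNAs than with the NT shRNA. With the RfxCasR NT gRNA they were higher by 0.158 log2. Between the NT array and NT gRNA no 7-mer passed with higher values. All 3 shifts use the same NT shRNA libraries, and a match of the NT shRNA to this 7-mer could not be judged.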

How the results depend on the processing

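Of the alternatives, exchanged array labels, a model without the array libraries and a separate variance for them were chosen after seeing the data. The shRNA counts stayed within 1.5 times of 7089 and 6077 under every alternative but the stricter threshold (adjusted p under 0.10 and a log2 change of at least 0.75). That gave 491 and 285 genes with the ANXA4 and B4GALNT1 shRNAs, 6 with the array, 314 and 582 for the differences between methods for B4GALNT1 and ANXA4, 250 between the NT gRNA and NT shRNA, and 418 between the NT array and NT gRNA, by its construction. At that stricter threshold the authors' deposited tables gave 1192 and 755 genes with the ANXA4 and B4GALNT1 shRNAs, 2 with the gRNA and 3 with the array. Fold changes here, of log2(FPKM + 1), understate the change of low genes, and whether this explains the gap was not tested. With the B4GALNT1 gRNA, at an adjusted p under 0.05, 2 genes were called in the authors' deposited table, 3 without the 6 array libraries and 4 with a separate variance for them. For the arrays the 39 genes became 3 with only the groups compared, 7 with a separate variance, 114 with voom on the recovered reads and 8 in the authors' deposited table; the separate variance acts through the larger spread of these libraries, and for the others the cause was not tested. With exchanged array labels the ANXA4 change reversed to -1 log2 by construction, and 3 of 10 genes named for the ANXA4 difference between methods reversed: SNORD18B (-1.515), MIR4743 (-1.337) and SNORD50B (0.094). A further 4 lost their call: ANXA4 (0.022), MIR7706 (0.076), MIR6827 (-0.559) and SNORD124 (-0.434).

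Leaving out 1 library gave 6384 to 6532 genes with the ANXA4 shRNA, 5309 to 5457 with the B4GALNT1 shRNA, 1 with the B4GALNT1 gRNA, 23 to 55 with the array (23 without replicate 2 labelled ANXA4 array), 3576 to 3742 and 4926 to 5443 for the differences for B4GALNT1 and ANXA4, 5766 to 5899 between the NT gRNA and NT shRNA, and 6911 to 7526 between the NT array and NT gRNA. Target changes ranged from -1.057 to -0.967 and -0.46 to -0.39 log2 with the shRNAs, -1.178 to -0.993 with the gRNA and 0.91 to 1.055 with the array as labelled. ANXA4 in the gRNA comparison, 0.035 log2 and never called, was -0.009 without replicate 2 of the NT gRNA. Of 1782 values of named genes with 1 library left out, 90 lost their call.

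The replicate numbers were not taken to pair the samples, since no comparison had all same-numbered correlations of deviations above 0.1 (-0.15 to 0.059 for the arrays, 0.033 to 0.072 for the B4GALNT1 gRNA and its control, where 6 of 6 samples correlated best with their own number). With a replicate block the counts were 7111, 6099, 2 and 34 for the 2 shRNAs, the gRNA and the array, 4128 and 5428 for the differences, and 6707 and 7791 for the controls; the second gene with the gRNA was MBLAC1 (-0.639 log2).

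Of 21 list calls, 2 held with an estimated correlation, and 20 each under the replicate block and with median-centred libraries, in the same direction. The overlap of the shRNAs, 3415 genes in the same direction, stayed within 1.5 times. Without regression on 3' untranslated region length and GC content, the number of 7-mers passing went from 22 to 36 and from 34 to 230 with the ANXA4 and B4GALNT1 shRNAs, from 2 to 307 with the gRNA and from 2 to 4284 with the array, so those counts depend on the correction. Depth and spread limit small changes: of simulated changes of 0.25 log2, 42% were recovered in the gRNA comparison and 16% with only the 6 array libraries.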

Other observations

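Of the genes of the RNA interference machinery, 4 of 13 rose and 5 fell with the ANXA4 shRNA, and 2 rose and 4 fell with the B4GALNT1 shRNA (limma, adjusted p under 0.05); the list was called in neither (camera adjusted p = 0.982 in both). DICER1, which processes hairpin precursors, rose with both, from 9.88 to 14.8 and to 15.7 FPKM. XPO5, the nuclear exporter of hairpins, rose with the ANXA4 shRNA (from 39.9 to 50.5 FPKM) and fell with the B4GALNT1 shRNA (to 30.7). AGO1 fell with the ANXA4 shRNA, to 3.78 FPKM, and was at 12.2 with the B4GALNT1 shRNA, against 11.4 in the control. Of 25 let-7 target genes, 12 rose and 3 fell with the ANXA4 shRNA (camera adjusted p = 0.0849) and 10 rose and 6 fell with the B4GALNT1 shRNA (camera adjusted p = 0.242). LIN28B rose from 19.9 to 34.8 FPKM with the former.

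Interferon-stimulated genes were not called as a list in any of the 4 main comparisons. In each of these the control carried the same kind of reagent, so a response common to both groups would not show. The lists were not tested between the control groups. The same holds for the RNA interference and let-7 lists above. With the ANXA4 shRNA 1 of 21 rose and 5 fell, among them BST2, which restrains virus release, from 5.07 to 1.55 FPKM. With the B4GALNT1 shRNA 2 rose and 5 fell, and with the gRNA and the array 0 were called. Markers of blood, fibroblast and endothelial cells, of which 6 were measured, had 2 higher and 2 lower with the ANXA4 shRNA.

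The tests of sequence shared with the targets and of 7-mers in the 4 main comparisons were written before their results; the 7-mer test between control groups was chosen after the result with the shRNAs was seen. A search over 16383 7-mers tested whether genes with a given sequence in the 3' untranslated region had other fold changes than genes without it, after regression on length and GC content. An annotated region was found for 11988 of 13679 genes (87.6%); genes are not independent replicates, so this is a ranking. In 5 data sets made by permuting the RfxCasR B4GALNT1 gRNA fold changes over genes, a 7-mer planted at -0.1 log2 ranked first each time. Over all tested genes those fold changes had an SD of 0.108 log2, against 0.333 and 0.283 with the ANXA4 and B4GALNT1 shRNAs. Permuting also removes any link of fold change to sequence. These data sets therefore cannot show how well smaller shifts, or shifts in the shRNA comparisons, are found, nor how often 7-mers pass falsely. With the ANXA4 shRNA, the 1309 genes with GATGACA were lower by 0.141 log2 at the median (n = 1309 genes with it, rank-sum test, Bonferroni p = 5.82e-46), and 44.0% of them were called lower, against 25.2% of the others. This 7-mer occurs in ANXA4 transcripts. So do GCACTTT and TTTGCAC, though not AGCACTT, which led on the lower side between the NT gRNA and NT shRNA, where ANXA4 was not targeted. Occurrence in transcripts of the target therefore does not tie a 7-mer to the shRNA. With the B4GALNT1 shRNA the lowest ranks were held by GCTGCCT (-0.053 log2, n = 2534 genes with it, Bonferroni p = 1.98e-19) and GTCAGGA (-0.057, n = 2084, Bonferroni p = 8.18e-18), both of which occur in transcripts of B4GALNT1 and of ANXA4. On the higher side, CTACCAA and TCTACCA led with both shRNAs. The 1037 genes with CTACCAA were higher by 0.14 and 0.118 log2 with the targeting shRNAs than with the NT shRNA, and by 0.158 with the RfxCasR NT gRNA than with the NT shRNA. The 2 RfxCasR knockdown comparisons had 2 passing 7-mers each, with shifts of at most 0.042 log2 in size. Between the NT array and NT gRNA, both RfxCasR, 64 passed, all with lower values, among them GCGGGGG (-0.057 log2) and GGGGGCT (-0.046), so shifts of the size seen with the B4GALNT1 shRNA also arose without an shRNA. The shift of -0.141 with the ANXA4 shRNA was larger than those of the leading 7-mers between RfxCasR groups. In size, the shift of -0.053 with the B4GALNT1 shRNA was not set apart from them. Its Bonferroni p was lower than that of GGGGGCT between the NT array and NT gRNA (rank-sum test, 3.97e-07). The leading 7-mers on the lower side overlapped, sharing ATGAC with the ANXA4 shRNA and, GCTGCCT aside, GTCAG with the B4GALNT1 shRNA. Whether an shRNA lowers genes that match a short stretch of it stays open. The shRNA sequences were not used, so the 7-mers could not be set against them. Of the genes called lower with the ANXA4 shRNA, 576 have GATGACA.

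RFXANK was lower with both reagents aimed at B4GALNT1, from 32.4 to 11 FPKM with the shRNA and, not called, from 28.3 to 21.8 with the gRNA. A stretch of sequence shared with B4GALNT1 was tested as a candidate explanation. The longest exact match between its longest transcript and B4GALNT1 transcripts was 13 bases, at the 43.3 percentile of 13109 genes. Of genes with transcripts of like length, 36.7% shared at least as many bases. This argues against an unusually long exact stretch shared with B4GALNT1. A match to the shRNA or the gRNA themselves could not be judged, since their sequences were not used. Matches with mismatches were not searched. For ANXA11, which differed with ANXA4 between the arrays, the longest exact match with ANXA4 transcripts was 22 bases, at the 82.1 percentile. As many bases were shared by 17.9% of genes, so a shared stretch can be neither singled out nor excluded for ANXA11.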
